A study of Mus musculus with 9 samples.

How the data were processed

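The data were gene expression values from mouse embryonic stem cells, measured on an Affymetrix whole-transcript array with biotin-labelled sense-strand target made from total RNA. Per the labels, 9 arrays fell into 3 groups of 3 biological replicates. Flox cells, named as controls in the labels, had lost 1 allele of β-catenin and carried a floxed second allele. Null cells had both alleles deleted. Null Eα cells were null cells that stably expressed a fusion of E-cadherin and α-catenin. The growth protocol in the labels gives gelatin-coated plates, 15% fetal calf serum and 1000 U/ml leukaemia inhibitory factor (LIF), with harvest before confluence. It names no feeder layer. The labels do not say whether the replicates of a group were independent lines or cultures of 1 line. The spread between replicates, on which the tests rest, was therefore read as the spread between cultures, and a difference between groups as a difference between genotype and line together.

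The deposited table held log2 RMA values, 1 per transcript cluster and array, made by the authors with RMA (no version given), per the submitters' processing notes. It listed 35556 features with values from 2.02 to 13.92. Each array's own values were used as deposited, with no background or between-array step added. The interquartile range over all features was 3.75 to 3.84 on the flox arrays, 3.41 to 3.46 on the null arrays and 3.21 to 3.37 on the null Eα arrays, so the arrays did not share 1 distribution. The labels do not say whether the 9 arrays were normalized together, and if the groups were normalized apart, every difference between groups would carry that step as well. Probe-level files, detection calls, and slide or scan dates were not used here. Precision was limited by the number of arrays per group.

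Gene names came from a table that pairs the array's features with genes. It listed 23410 of the features, 21789 with 1 symbol and 1621 with several, and 12146 features were not in it. Of the features with 1 symbol, 21698 had an Entrez ID in a reference gene table of the assembly GRCm38.p6 and 91 had none, and 0 symbols needed an update. That table served only for chromosome numbers and gene order, and no coordinates are given. Features with several symbols were left out. Of the 999 genes with several features, the feature with the highest mean over the 9 arrays was kept, which gave 19938 genes. Among called genes with several features, another feature had the opposite sign in 146 of 703 for null against flox, 172 of 744 for null Eα against flox and 49 of 407 for null Eα against null.

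Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group, all 9 arrays in 1 fit, 6 residual and 4.04 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes, separately for each of the 3 comparisons. Errors after ± are limma's standard errors. The deleted gene and 3 other junction genes were also tested with an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

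Before the data were examined, 23 gene lists with 460 members were fixed, covering pluripotency, signalling, lineages, cell contacts, matrix, stress, metabolism, imprinted and germline genes, and fibroblast markers as a check for cells of another type. Of the members, 426 were matched to a tested gene. Members without a match, among them T, Tcf7, Ccnb1 and H19, were not analysed here. The 21 lists with at least 5 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The 2-cell-like list and the list of sex-chromosome genes had too few members to test. Members were also adjusted over the list alone.

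Genes were named by a rule fixed before the data were examined. It took the 6 largest rises and the 6 largest falls per comparison among called genes whose groups did not overlap, leaving out predicted and clone-based symbols, olfactory and vomeronasal receptors, small RNA genes and features with several symbols. It added the 3 members with the smallest p of each called list, and always Ctnnb1, Jup, Cdh1, Ctnna1, Axin2, Pou5f1 and Nanog. It also took the 5 genes with the largest smaller change among genes that moved back toward flox with the fusion, and likewise among genes that differed from flox alike in both lines. A further 22 genes were named after their values were seen: Krt8, Rian, Mest, Sgce, Fgf5, Otx2, Notum, Znrf3, Gprc5c, Kctd12b, Pdgfc, Tia1, Fn1, Lin28a, Tdgf1, Lum, Meox1, Usp17la, Xist, Eif2s3y, Kdm5d and Uty.

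A gene was counted as moved back when it was called in null against flox and called in the opposite direction in null Eα against null, and as alike when it was called in the same direction against flox in null and in null Eα. Genes that moved past the flox level to its other side also counted as moved back. The first pair of comparisons shares the null arrays and the second shares the flox arrays. Values for unchanged groups were therefore simulated 100 times, with noise independent between genes. The simulation shows what replicate noise in shared arrays adds to correlations and covariances, but not to overlaps of calls among changed genes. Shifts of chromosomes were taken over the brighter genes (mean level above the median) as the median difference from genes of other chromosomes matched on mean level. The 95% intervals of these shifts came from 1000 bootstrap resamples of genes with the arrays held fixed. They treat genes as independent and carry no spread between cultures or lines. List medians were set against 10000 random lists matched on mean level.

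The fit and the list test were tested on simulated data with 200 changed genes. Changes of 2-fold were recovered in 98%, 100% and 100% of cases for null against flox, null Eα against flox and null Eα against null, and changes of 0.5 log2 units in 56%, 68% and 68%. Of the calls in those simulations, 4.94%, 4.00% and 6.67% were false. The list shifted in the simulation, cholesterol synthesis, was called each time, with 0 of the other lists. The simulated noise was independent between genes, whereas the estimated correlation of that list in the data was 0.807. The simulation therefore does not test the list calls where members vary together. Alternatives fixed before the data were examined were quantile normalization of the table, centring of each array on its median, leaving out genes below the 40th percentile of mean level, the mean of a gene's features, eBayes with trend and robust prior, a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum, an estimated correlation for the lists, and leaving out each array in turn. Centring each chromosome was added after the chromosome shifts had been seen.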

Results

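Transcript levels were measured in mouse embryonic stem cells of 3 genotypes, with 3 arrays per group and 9 arrays in all. Flox cells kept 1 floxed allele of the β-catenin gene, null cells had neither allele, and null Eα cells were null cells with a stably expressed E-cadherin and α-catenin fusion, which links the cadherin to α-catenin without β-catenin. Values were log2 RMA signals for 19938 genes, and the median over all features lay between 5.95 and 6.06 on every array. Pearson correlations across features were 0.995 to 0.997 between flox arrays, 0.991 to 0.992 between null arrays and 0.986 to 0.990 between null Eα arrays. Between groups they were 0.935 to 0.941 for flox and null, 0.945 to 0.956 for flox and null Eα, and 0.964 to 0.980 for null and null Eα. Null Eα replicate 3 stood nearer to the null arrays, at 0.978 to 0.980, than null Eα replicates 1 and 2, at 0.964 to 0.970. Features within an array are not independent replicates.

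The deleted gene was lower in both lines without β-catenin. Ctnnb1, which encodes β-catenin (transcript cluster 10590325), fell by 0.65 ± 0.07 log2 units in null cells, from a mean of 11.16 to 10.51 (limma, Benjamini-Hochberg adjusted p = 2.82e-05, n = 3 arrays per group), which left 63.7% of the flox signal. In null Eα cells it fell by 0.93 ± 0.07 (adjusted p = 2.66e-06), which left 52.5%. An exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 arrays against 3 allow. The array value covers the whole transcript cluster, and probes outside the deleted exons do not test the deletion, so the remaining signal is no measure of intact β-catenin mRNA. The further difference between null Eα and null was -0.28 ± 0.07 (adjusted p = 0.0156), a call lost without null Eα replicate 2 (-0.23) and after quantile normalization (-0.18), with adjusted p from 0.00354 to 0.0881 over 17 alternatives.

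Transcripts of β-catenin's partners at the adherens junction moved in different directions. Ctnna1, which encodes α-catenin, rose by 1.04 ± 0.07 in null cells and by 0.99 ± 0.07 in null Eα cells (adjusted p = 9.34e-07 and 1.81e-06), and the lines differed by -0.05 ± 0.07 (adjusted p = 0.638). Ctnna1 lies on chromosome 18, whose brighter genes shifted by 0.17 in null and 0.21 in null Eα cells against flox. Jup, which encodes plakoglobin, the close relative of β-catenin, lay at -0.71 ± 0.10 and -1.25 ± 0.10 (adjusted p = 1.79e-04 and 3.58e-06), a fall in both lines. Cdh1, which encodes E-cadherin, differed by -0.17 ± 0.07 in null cells (adjusted p = 0.0755, 0.0214 to 0.563 over 17 alternatives) and fell by 0.26 ± 0.07 in null Eα cells (adjusted p = 0.0102). Cdh1 lies on chromosome 8, whose brighter genes as a group were lower in both lines. The null difference was called with a trend and robust prior (adjusted p = 0.0214) and turned to 0.06 with each chromosome centred. The null Eα call was lost after quantile normalization (-0.15) and turned to 0.07 with each chromosome centred, with adjusted p from 0.00146 to 0.511 over 17 alternatives. The features of Cdh1 and Ctnna1 were no higher in null Eα than in null cells, so the fusion transcript was not visible in them.

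**Figure D1:**
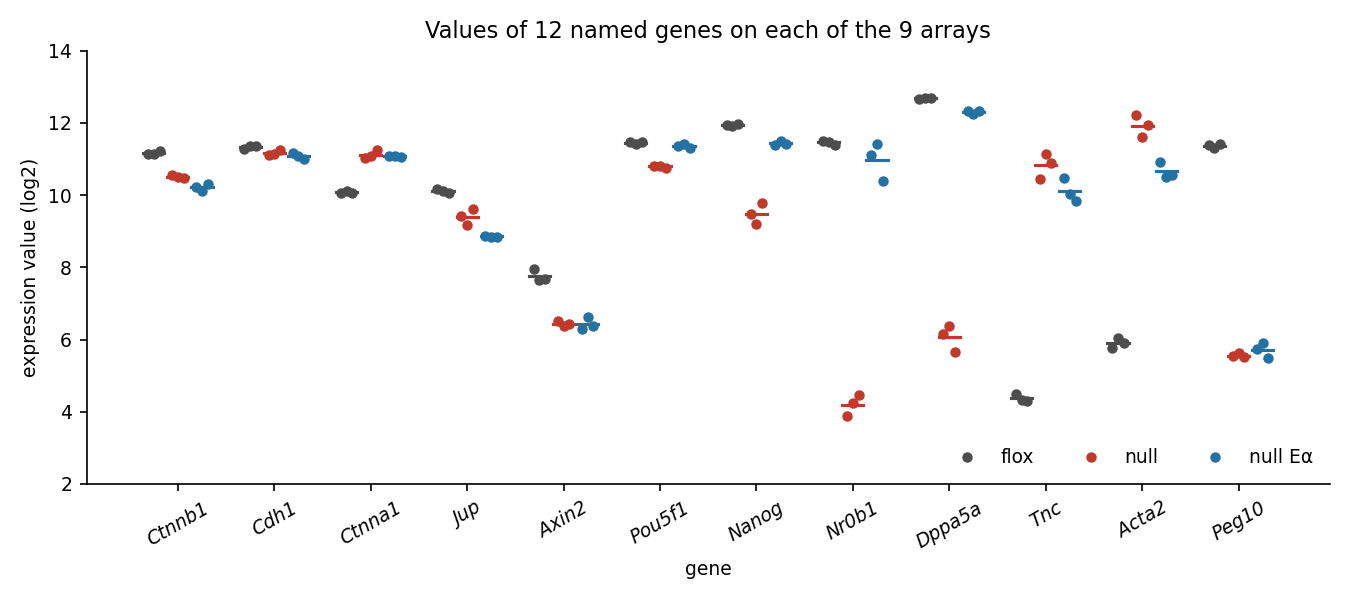
Log2 RMA signal (vertical axis) of 12 genes (horizontal axis) on each of the 9 arrays, with groups in colours, points for arrays and lines for the means of 3 arrays. Ctnnb1 was lower in both lines without β-catenin, Nr0b1 and Dppa5a were low in null cells alone, and Peg10 was low in null and null Eα cells.

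Null against flox cells shows what differs when the second β-catenin allele is deleted as well. Genes of the naive pluripotency network were far lower in null cells. Of the 27 measured genes of naive and core pluripotency, 25 fell and 2 rose, with a median change of -3.17 log2 units. Nr0b1, a nuclear receptor of naive stem cells (transcript cluster 10600707), fell by 7.27 ± 0.23 (n = 3 arrays per group, limma adjusted p = 3.87e-09). Its null mean of 4.19 lay below the lower quartile of all features on the null arrays (4.52 to 4.55), and signal over background was not measured, so this and other differences from so dim a level, as in Dnmt3l, Zfp640 and Zfp980 below, are lower bounds. Dppa5a, an RNA-binding protein of pluripotent cells, fell by 6.62 ± 0.15, Esrrb, a transcription factor of the naive state, by 5.54 ± 0.16, Pecam1, an adhesion molecule, by 4.19 ± 0.08 and Sox15, a Sox factor, by 3.32 ± 0.09. Of the core factors, Nanog changed by -2.46 ± 0.12 (adjusted p = 9.20e-08) and Pou5f1, which encodes Oct4, by -0.65 ± 0.07 (adjusted p = 1.13e-05). The 2 genes that rose were Lin28a, an RNA-binding protein (0.44 ± 0.09), and Tdgf1, a Nodal co-receptor (0.27 ± 0.10, adjusted p = 0.0402), whose call was lost when any flox array, null replicate 1 or null replicate 3 was left out (0.20 to 0.29) and with each chromosome centred (0.17). The list passed limma's camera test (adjusted p = 3.39e-13), with adjusted p = 0.180 with an estimated correlation. When adjusted over the list alone, the counts were again 25 and 2.

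Germline genes were lower in null cells as well. Of 16 germline genes 14 fell and 0 rose, 15 when adjusted over the list alone, with a median of -2.04 (camera adjusted p = 2.16e-07, adjusted p = 0.323 with an estimated correlation). Among them Dnmt3l, the cofactor of de novo DNA methylation, fell by 6.32 ± 0.16, Mael, of the piRNA pathway, by 3.78 ± 0.10, and Dazl, a germ-cell RNA-binding protein, by 3.69 ± 0.08. The remaining genes among the 6 largest falls named by rule were the zinc finger genes Zfp640 (-6.52 ± 0.15) and Zfp980 (-6.49 ± 0.25) and Rpp25, a subunit of ribonuclease P (-6.23 ± 0.23). Of 19 cell cycle genes 11 fell and 2 rose, with the same counts when adjusted over the list alone (median -0.34, camera adjusted p = 0.0460, adjusted p = 0.323 with an estimated correlation). Ccnd3, a G1 cyclin, fell by 2.11 ± 0.08, Ccnb2, a mitotic cyclin, by 1.27 ± 0.11, and Mcm5, a subunit of the replicative helicase, by 0.93 ± 0.08. Mcm5 lies on chromosome 8, where the brighter genes shifted by -0.42. The cell cycle call was lost under 8 of 17 alternatives, over which its adjusted p ran from 0.0395 to 0.272, among them the fits without flox replicate 2, flox replicate 3 or null replicate 3 (medians -0.33, -0.31 and -0.31).

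Tnc, which encodes the matrix protein tenascin C (transcript cluster 10513739), rose by 6.45 ± 0.19 in null cells (limma adjusted p = 2.74e-09), a lower bound too, since its flox mean of 4.37 lay at the lower quartile of the flox arrays (4.37 to 4.40). Anxa1, a phospholipid-binding annexin, rose by 6.34 ± 0.11, Acta2, smooth muscle actin, by 6.01 ± 0.16, Slc39a8, a zinc transporter, by 5.97 ± 1.12, Thbs1, a matrix glycoprotein, by 5.91 ± 0.10 and Lox, which crosslinks collagen, by 5.41 ± 0.12. The wide error of Slc39a8 comes from the null Eα arrays (5.78, 5.54 and 10.91) through the shared fit. Its SD was 0.36 on the null and 0.04 on the flox arrays. Of 23 integrin and extracellular matrix genes 14 rose and 5 fell, 15 and 5 when adjusted over the list alone (camera adjusted p = 0.00575, adjusted p = 0.180 with an estimated correlation), among them Cd44, the hyaluronan receptor (3.39 ± 0.13). Of 20 mesenchymal genes 12 rose and 2 fell, 12 and 3 when adjusted over the list alone (camera adjusted p = 3.36e-04, adjusted p = 0.180 with an estimated correlation), among them Tagln, an actin-binding protein (4.74 ± 0.16), and Mmp14, a membrane metalloprotease (2.61 ± 0.11). Markers of fibroblasts, a cell type of feeder layers, moved with both lists. Of 14 fibroblast markers 12 rose and 0 fell, 13 when adjusted over the list alone, with a median of 3.20 (camera adjusted p = 1.77e-07, adjusted p = 0.180 with an estimated correlation). Col1a2, a chain of collagen I, rose by 4.82 ± 0.12, from a mean of 6.20 to 11.02. Lum differed by 1.54 ± 0.66 (adjusted p = 0.0710), called when any 1 null array was left out (0.51 without replicate 2, up to 2.06 without the others), and Meox1 by -0.09 ± 0.08. Fn1, fibronectin, which fibroblasts make in quantity, fell by 0.53 ± 0.10. Acta2 belongs to the mesenchymal list as well.

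Junction genes outside the adherens junction also rose in null cells. Of 23 genes of desmosomes and tight junctions 14 rose and 2 fell, 15 and 3 when adjusted over the list alone (median 0.37, camera adjusted p = 0.0216, adjusted p = 0.616 with an estimated correlation). Dsc2, a desmosomal cadherin, rose by 3.38 ± 0.16, Dsp, desmoplakin, by 2.43 ± 0.23, and Cgn, the tight-junction protein cingulin, by 1.77 ± 0.12. Cldn4, a claudin, fell by 1.23 ± 0.13. The simple-epithelium keratins Krt8, Krt18 and Krt19 rose by 3.06 ± 0.10, 2.79 ± 0.20 and 2.82 ± 0.45.

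Most genes taken as direct Wnt/β-catenin targets were not called in null cells. Of 21 measured targets 6 fell and 2 rose, with the same counts when adjusted over the list alone, and the list was not called (camera adjusted p = 0.352, adjusted p = 0.814 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, fell by 1.32 ± 0.11 (adjusted p = 2.75e-06). Notum and Znrf3, also feedback inhibitors, fell by 2.48 ± 0.22 and 1.58 ± 0.08. Of the 6 falls 5 were at least 2-fold, and of the 2 rises 0 were. Whether the targets not called lay above background in flox cells was not measured, and a gene at background cannot show a fall. Of 38 Wnt pathway components 15 rose and 9 fell (adjusted p = 0.352), and of 20 genes of the adherens junction 7 rose and 9 fell (adjusted p = 0.565). Counts of rising and falling genes were 5 and 6 of 17 for LIF-STAT3 signalling (adjusted p = 0.858), with Lifr, the LIF receptor, at -3.03 ± 0.13, and 6 and 7 of 18 for Nodal, TGF-β and BMP signalling (0.699), with the TGF-β ligand Gdf3 at -4.53 ± 0.20.

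Lineage lists were mixed in null cells. Primed epiblast genes gave 10 rises and 5 falls of 16 (camera adjusted p = 0.243), including rises of Fgf5, a growth factor of the primed epiblast (3.75 ± 0.61), and Otx2, a homeobox factor of the same stage (1.27 ± 0.28). The counts of rising and falling genes were 9 and 4 of 20 for primitive streak and mesendoderm, 13 and 6 of 25 for primitive and visceral endoderm, and 4 and 7 of 17 for trophectoderm (each camera adjusted p = 0.352). For neuroectoderm they were 9 and 7 of 19 (adjusted p = 0.858), for p53 targets 9 and 3 of 14 (0.108), for hypoxia and glycolysis 8 and 4 of 19 (0.352), for cholesterol synthesis 5 and 5 of 15 (0.962) and for imprinted genes 6 and 7 of 18 (0.858). The p53 list was called after quantile normalization, with adjusted p from 0.0263 to 0.190 over 17 alternatives. The cholesterol list had a median of -0.12 and a mean of 0.10. When adjusted over the list alone, the counts of the lists not called were the same except for 10 and 3 for p53 targets, 15 and 10 for Wnt pathway components and 7 and 8 for imprinted genes. Of the 3 measured 2-cell-like genes 0 were called, and of the 4 sex-chromosome genes 2, Xist and Eif2s3y, rose. The others, Kdm5d (0.96) and Uty (0.38), were called higher too without null Eα replicate 2 and when only the groups compared were fitted. For both, every null array lay above every flox array.

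Across all genes, 11004 of 19938 were called in null against flox (55.2%), 5285 higher and 5719 lower. The balance turned with each array centred on its median, at 7121 higher and 5205 lower, and was 3369 higher and 5103 lower with dim genes left out. At least 2-fold, 1003 were higher and 2042 lower, and at least 8-fold 64 were higher and 138 lower. Many calls were of small shifts, and the median over all genes was 0.06. Line and genotype cannot be separated here, since the labels do not give independent lines.

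Null Eα against flox cells shows what still differs from control in cells without β-catenin that carry the fusion. Tnc rose by 5.74 ± 0.19 (limma adjusted p = 2.24e-08, n = 3 arrays per group), Thbs1 by 5.28 ± 0.10, Anxa1 by 5.11 ± 0.11, Acta2 by 4.74 ± 0.16 and the matrix protease gene Mmp3 by 4.74 ± 0.60. Usp17ld rose by 5.38 ± 0.47, but this deubiquitinase gene belongs to a family of near-identical copies, so its value is uncertain. Peg10, an imprinted gene derived from a retrotransposon, fell by 5.66 ± 0.10 (adjusted p = 1.23e-09).

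Of the 27 pluripotency genes 19 fell and 1, Tdgf1 (0.69 ± 0.10), rose, with the same counts when adjusted over the list alone (median -0.56, camera adjusted p = 0.00161, adjusted p = 0.427 with an estimated correlation). The list's median lay 0.26 below that of random lists of like mean level (-0.30), of which 398 of 10000 lay as low. Sox15 fell by 1.72 ± 0.09, Pecam1 by 1.57 ± 0.08 and Fgf4, a growth factor of stem cells, by 1.27 ± 0.09. Nanog fell by 0.51 ± 0.12 (adjusted p = 0.00510), and Pou5f1 differed by -0.09 ± 0.07 (adjusted p = 0.264). Sox15 and Pecam1 lie on chromosome 11 and Nanog on chromosome 6, whose brighter genes shifted by -0.38 and -0.37. The list's call was lost when dim genes were left out, with adjusted p from 2.57e-04 to 0.121 over 17 alternatives. Of 16 germline genes 8 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00530, adjusted p = 0.566 with an estimated correlation), among them Dazl (-2.88 ± 0.08), Mael (-2.61 ± 0.10) and Sohlh2, a germline transcription factor (-2.44 ± 0.11). That call too was lost without dim genes, with adjusted p from 3.93e-04 to 0.353 over 17 alternatives.

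Fibroblast markers moved with the matrix and mesenchymal lists in null Eα cells as they did in null cells. Of 14 fibroblast markers 12 rose and 0 fell, with the same counts when adjusted over the list alone (median 2.24, camera adjusted p = 5.38e-06, adjusted p = 0.384 with an estimated correlation), among them Lox (4.44 ± 0.12) and Col1a2 (3.65 ± 0.12). Of 23 integrin and matrix genes 13 rose and 5 fell (camera adjusted p = 0.0404) and of 20 mesenchymal genes 11 rose and 2 fell (camera adjusted p = 0.0227), with the same counts when adjusted over the list alone, each with adjusted p = 0.384 with an estimated correlation. Cd44 rose by 3.14 ± 0.13, Tagln by 3.00 ± 0.16 and Mmp14 by 1.73 ± 0.11. The integrin and matrix call was lost when each array was centred on its median and when only the groups compared were fitted, and its adjusted p ran from 8.64e-04 to 0.0641 over 17 alternatives. Of 19 cell cycle genes 11 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00813, adjusted p = 0.384 with an estimated correlation). Ccnd3 fell by 1.64 ± 0.08, Mcm2, of the replicative helicase, by 1.12 ± 0.08 and Cdk1, the mitotic kinase, by 1.10 ± 0.08. Mcm2 lies on chromosome 6, and the cell cycle call was lost after quantile normalization and without dim genes, with adjusted p from 0.00672 to 0.181 over 17 alternatives.

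The other largest falls in null Eα cells were Uqcc2, an assembly factor of respiratory complex III (-4.16 ± 0.09), Obox6, an oocyte homeobox gene (-4.12 ± 0.11), Terc, the RNA of telomerase (-3.84 ± 0.11), Apela, a peptide ligand of the apelin receptor (-3.77 ± 0.29), and Ceacam1, an adhesion molecule (-3.48 ± 0.13). Apela lies on chromosome 8, whose brighter genes shifted by -0.40, and Peg10 on chromosome 6. Wnt/β-catenin targets gave 8 rises and 7 falls of 21 (camera adjusted p = 0.978, median 0.14 and mean -0.16). Axin2 fell by 1.33 ± 0.11 (adjusted p = 3.43e-06), Notum by 1.35 ± 0.22 and Znrf3 by 1.43 ± 0.08, and these 3 genes lie on chromosome 11. Adherens junction genes gave 3 rises and 12 falls of 20 (adjusted p = 0.0547). Primitive streak and mesendoderm genes gave 10 rises and 1 fall of 20, and primitive and visceral endoderm genes 15 and 5 of 25 (each adjusted p = 0.0601). These 3 lists were called under 4, 2 and 2 of 17 alternatives, with adjusted p from 0.0443 to 0.739, 0.0443 to 0.121 and 9.53e-04 to 0.0993. The adherens list was called without null replicate 1, null replicate 2 or null Eα replicate 1 (medians -0.26, -0.26 and -0.28), the streak list without flox replicate 1 or null Eα replicate 1 (0.35 for both) and the endoderm list without null Eα replicate 3 (0.49).

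Desmosome and tight junction genes gave 5 rises and 4 falls of 23 (adjusted p = 0.885), with Krt8 up by 0.41 ± 0.10, Krt18 at -0.40 ± 0.20 (adjusted p = 0.0982) and Krt19 at -0.33 ± 0.45 (adjusted p = 0.525). Without null Eα replicate 3, Krt18 and Krt19 were called at -0.63 and -1.01. With the replicate block Krt18 was called as well (-0.40, limma adjusted p = 0.0170). The remaining counts of rises and falls were 14 and 12 of 38 for Wnt pathway components (adjusted p = 0.975), 6 and 4 of 17 for LIF-STAT3 signalling (0.479), 7 and 3 of 18 for Nodal, TGF-β and BMP signalling (0.577), 7 and 3 of 16 for primed epiblast (0.416), 7 and 4 of 19 for neuroectoderm (0.652) and 3 and 7 of 17 for trophectoderm (0.455). They were 5 and 2 of 14 for p53 targets (0.479), 5 and 5 of 19 for hypoxia and glycolysis (0.885), 4 and 8 of 15 for cholesterol synthesis (0.479) and 8 and 8 of 18 for imprinted genes (0.597). Of the 2-cell-like genes 1 of 3 rose (Usp17la, 0.45 ± 0.13), a member of the multi-copy deubiquitinase family. Its call was lost under 3 of 16 alternatives, 1 of them without flox replicate 2 (0.35). Of the 4 sex-chromosome genes 1 rose (Xist, 1.17 ± 0.16). Without null Eα replicate 2, Eif2s3y and Uty were called higher too, at 0.73 and 0.27. Without null Eα replicate 3, Kdm5d was called lower, at -1.20. The LIF-STAT3 list was called after quantile normalization, with adjusted p from 0.0424 to 0.577 over 17 alternatives. When adjusted over the list alone, the counts of the lists not called were the same except for 3 and 4 for desmosomes and tight junctions and 15 and 13 for Wnt pathway components.

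In null Eα against flox, 12694 of 19938 genes were called (63.7%), 6399 higher and 6295 lower. At least 2-fold, 442 were higher and 1944 lower. With dim genes left out 8430 genes were called, 68.5% of them lower, against 49.6% with all genes. The share of lower calls was 42.6% with each array centred on its median and 51.6% after quantile normalization.

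Null Eα against null cells shows what differs between 2 lines without β-catenin, 1 of which carries the fusion, and here too line and genotype cannot be separated. Pluripotency genes were higher with the fusion, 26 of 27 rising and 1, Lin28a (-0.30 ± 0.09), falling, with a median change of 2.10 log2 units. Lin28a lost its call under 5 of 17 alternatives, among them the fits without null replicate 1, null Eα replicate 1 or null Eα replicate 2 (-0.22, -0.27 and -0.28). The same counts held when adjusted over the list alone (camera adjusted p = 3.90e-22, adjusted p = 0.0838 with an estimated correlation). Nr0b1 rose by 6.78 ± 0.23 (limma adjusted p = 4.40e-08, n = 3 arrays per group), a lower bound as before, Dppa5a by 6.23 ± 0.15, Dppa2, a chromatin factor of pluripotent cells, by 5.37 ± 0.32 and Esrrb by 4.98 ± 0.16. Pecam1 rose by 2.62 ± 0.08, Nanog by 1.95 ± 0.12 (adjusted p = 3.87e-06) and Pou5f1 by 0.57 ± 0.07 (adjusted p = 1.54e-04). On null Eα replicate 3 the pluripotency and germline genes lay lower than on the other null Eα arrays, by medians of 0.23 and 0.23. Primed epiblast genes lay higher on that array by a median of 0.52, with 11 of 16 members above and 5 below.

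Germline genes were higher with the fusion as well, 10 of 16 rising and 0 falling, 13 and 0 when adjusted over the list alone (camera adjusted p = 2.00e-07, adjusted p = 0.236 with an estimated correlation). Dnmt3l rose by 6.09 ± 0.16, Ddx4, a germ-cell RNA helicase, by 2.65 ± 0.23 and Mael by 1.17 ± 0.10. The zinc finger genes Zfp980 and Zfp640 rose by 6.00 ± 0.25 and 5.62 ± 0.15. Of 17 LIF-STAT3 genes 6 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.236 with an estimated correlation). Lifr rose by 2.32 ± 0.13, Il6st, its partner receptor, by 0.46 ± 0.09 and Spry2, an inhibitor of growth factor signalling, by 1.08 ± 0.12. Of 18 genes of Nodal, TGF-β and BMP signalling 6 rose and 3 fell, 8 and 3 when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.236 with an estimated correlation), with Gdf3 up by 4.14 ± 0.20, Id2, an inhibitor of helix-loop-helix factors, by 1.05 ± 0.11 and Tgif1, a repressor of TGF-β signalling, by 0.67 ± 0.07. Of 20 primitive streak genes 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0473, adjusted p = 0.275 with an estimated correlation). Eomes, a T-box factor, rose by 1.07 ± 0.10, while the calls of Tal1 (0.31 ± 0.09) and Cyp26a1 (-0.69 ± 0.20) were lost when null replicate 1 was left out (0.29 and -0.47) or null Eα replicate 1 (0.25 and -0.56), and that of Tal1 also without null replicate 3 (0.28). The streak call was lost under 8 of 17 alternatives, with adjusted p from 0.0197 to 0.122, among them the fits without flox replicate 2, null replicates 1, 2 or 3, or null Eα replicate 3 (medians 0.13 to 0.22). That of the LIF-STAT3 list was lost without null replicate 3 (median 0.22) and without null Eα replicate 1 (0.18), with adjusted p from 0.00792 to 0.0630 over 17 alternatives.

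Desmosome and tight junction genes were lower with the fusion. Of 23 genes of desmosomes and tight junctions 15 fell and 2 rose, 16 and 2 when adjusted over the list alone (camera adjusted p = 3.34e-04, adjusted p = 0.275 with an estimated correlation), with Dsc2 at -2.58 ± 0.16, the tight-junction protein Ocln at -1.64 ± 0.16 and Cldn4 up by 1.34 ± 0.13. Krt18 fell by 3.19 ± 0.20, Krt19 by 3.15 ± 0.45 and Krt8 by 2.65 ± 0.10. Null Eα replicate 3 stood apart toward null here, its list members lying above the other null Eα arrays by a median of 0.33, with Dsp at 8.16 against 7.11 and 7.18 and Krt19 at 7.88 against 5.97 and 5.74. Outside the list, Slc39a8 was 10.91 on that array against 5.78 and 5.54. Of 20 adherens junction genes 9 fell and 1 rose, 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.325 with an estimated correlation). The member that rose was Lima1, an actin-binding protein (0.95 ± 0.09), while Cdh2, N-cadherin, fell by 1.02 ± 0.14 and Ajuba, a LIM protein, by 0.51 ± 0.08.

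Fibroblast markers fell alongside the mesenchymal and matrix lists. Of 14 fibroblast markers 7 fell and 0 rose (median -0.72, adjusted p = 0.236 with an estimated correlation), and of 20 mesenchymal genes 11 fell and 1 rose (median -0.55, adjusted p = 0.176 with an estimated correlation), each at a camera adjusted p of 1.54e-04 and with the same counts when adjusted over the list alone. Col1a2, Col1a1 and Lox fell by 1.17 ± 0.12, 1.11 ± 0.14 and 0.97 ± 0.12, and the changes of Tagln, Cald1, an actin-binding protein, and Mmp14 were -1.73 ± 0.16, -1.69 ± 0.14 and -0.88 ± 0.11. Of 23 integrin and matrix genes 11 fell and 2 rose, 11 and 3 when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.236 with an estimated correlation). Itga5, the fibronectin receptor subunit, fell by 1.01 ± 0.13, whereas Lama1, a laminin chain, and Col18a1, a basement membrane collagen, rose by 1.46 ± 0.13 and 1.04 ± 0.10. Col1a2 and Cald1 lie on chromosome 6 and Col1a1 on chromosome 11, whose brighter genes shifted by -0.38 and -0.29.

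Of 38 Wnt pathway components 12 fell and 4 rose, 14 and 6 when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.236 with an estimated correlation). Wls, the Wnt carrier, fell by 1.32 ± 0.10 and the receptor gene Fzd3 by 1.63 ± 0.20, and Porcn, which acylates Wnt proteins, rose by 1.55 ± 0.09. Wnt/β-catenin targets gave 4 rises and 1 fall of 21 (camera adjusted p = 0.0567, 0.0250 to 0.227 over 17 alternatives), and the list was called without flox replicate 3, null replicate 1 or null Eα replicate 3 (medians 0.15, 0.22 and 0.16). Axin2 differed by -0.01 ± 0.11 (adjusted p = 0.961), and Notum rose by 1.14 ± 0.22. Of 19 hypoxia and glycolysis genes 7 fell and 2 rose, 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.462 with an estimated correlation), with falls of Hk2, a hexokinase (-0.96 ± 0.08), and P4ha2, a collagen prolyl hydroxylase (-0.96 ± 0.13), and a rise of Pdk1, which inhibits pyruvate dehydrogenase (1.07 ± 0.16). Of 15 cholesterol synthesis genes 4 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.537 with an estimated correlation). The sterol enzyme Sc5d fell by 0.67 ± 0.14, while the calls of Dhcr7 (-0.67 ± 0.17) and Cyp51 (-0.54 ± 0.15) were each lost without null replicate 3 (-0.56 and -0.48), null Eα replicate 1 (-0.59 and -0.43) or null Eα replicate 2 (-0.53 and -0.46). On null Eα replicate 3, 15 of 15 members lay above the other null Eα arrays, by a median of 0.34. Calls of the Wnt component, adherens junction, integrin and matrix, hypoxia and cholesterol lists were lost after quantile normalization and without dim genes, and their adjusted p rose to at most 0.229, 0.195, 0.227, 0.195 and 0.229 over 17 alternatives. Leaving out null replicate 3 also ended the adherens, integrin and matrix, and cholesterol calls (medians -0.15, -0.30 and -0.12), leaving out null replicate 1 the hypoxia call (-0.19), and leaving out null Eα replicate 1 or 2 the cholesterol call (-0.18 for both).

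Among the other largest falls with the fusion were Tdrkh, a piRNA pathway protein (-3.72 ± 0.18), Cd59a, an inhibitor of complement (-3.71 ± 0.34), the ubiquitin ligase gene Herc6 (from a mean of 7.98 to 4.98) and the imprinted long noncoding RNA Meg3 (-2.95 ± 0.17). Lists not called were p53 targets with 2 rises and 6 falls of 14 (camera adjusted p = 0.0830, but called without null Eα replicate 3 at a median of -0.31), imprinted genes with 4 and 6 of 18 (0.195), cell cycle genes with 1 and 5 of 19 (0.215), primitive and visceral endoderm with 6 and 6 of 25 (0.378), primed epiblast with 5 and 7 of 16 and neuroectoderm with 4 and 4 of 19 (each 0.396) and trophectoderm with 4 and 4 of 17 (0.576), all with the same counts when adjusted over the list alone. Of the 2-cell-like genes 0 of 3 were called, and of the sex-chromosome genes 3 of 4 fell.

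Between null Eα and null cells 6330 of 19938 genes were called (31.7%), 2721 higher and 3609 lower, and at least 2-fold 339 were higher and 624 lower. Without null Eα replicate 3, 7859 genes were called. With an estimated correlation, camera called 0 of 21 lists in each comparison, and 4 lists in null against flox, 2 in null Eα against flox and 3 in null Eα against null had an unadjusted p under 0.05.

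**Figure D2:**
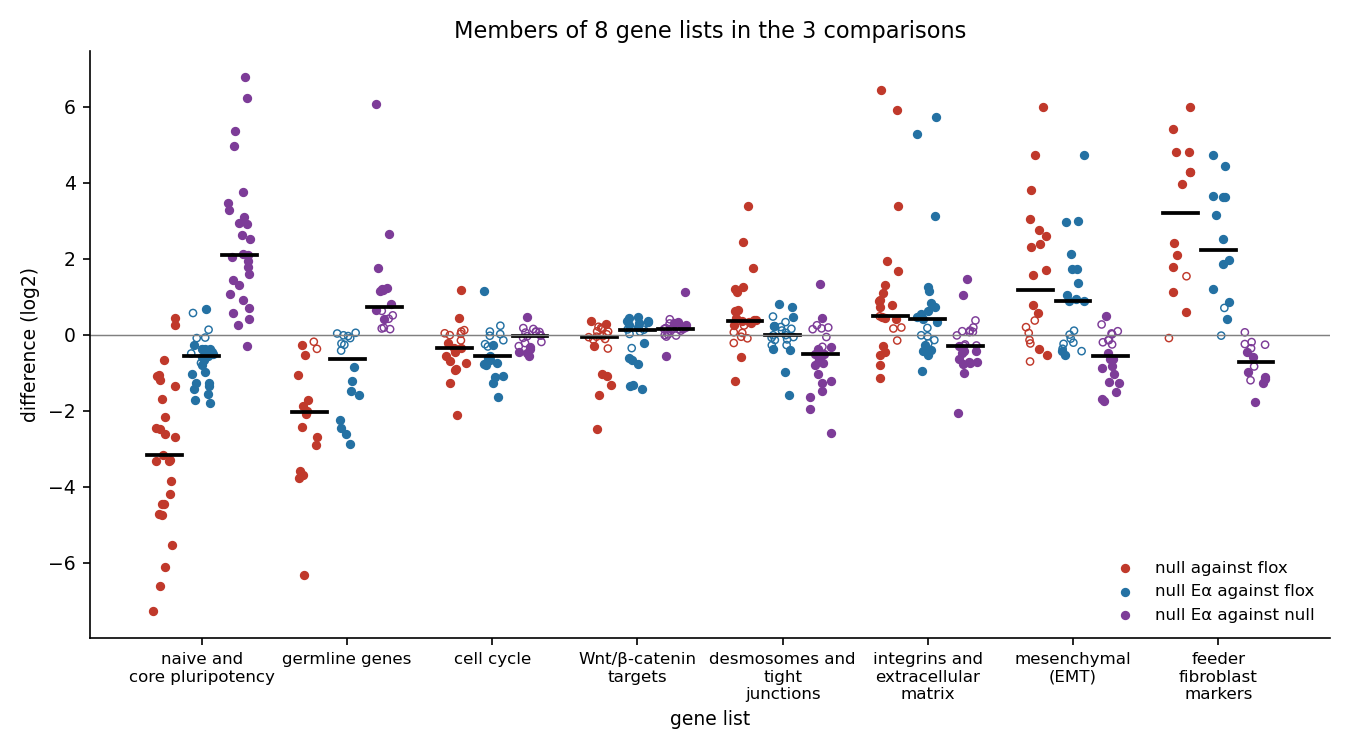
Log2 difference (vertical axis) of each measured member of 8 gene lists (horizontal axis) in the 3 comparisons (colours). Points are filled for called genes and open for others, and bars mark list medians. The pluripotency median was -3.17 in null and -0.56 in null Eα against flox, and that of the fibroblast markers was 3.20 and 2.24.

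Each gene changed in null cells was then followed into null Eα cells. Of the 11004 genes called in null against flox, 3493 (31.7%) moved back toward flox with the fusion and 8664 (78.7%) differed from flox in the same direction in both lines. Some did both, and 1919 genes counted under each. Of the 3493, 1355 were not called against flox in null Eα cells. A further 219 passed flox and were called on its other side. Another 1134 of the 11004 moved further from flox, called in the same direction in null Eα against null as in null against flox. Among the 2042 genes at least 2-fold lower in null cells 1005 moved back (49.2%), and among the 1003 at least 2-fold higher 747 did (74.5%). Moving back was mostly partial, since 1944 of the 2042 (95.2%) and 730 of the 1003 (72.8%) were still called on the same side of flox. Of the 1005 and 747 that moved back, 88 and 250 were not called against flox in null Eα cells. The genes that moved back with the largest changes were Nr0b1, Dppa5a, Dnmt3l, Zfp980 and Zfp640, and the remaining differences from flox in null Eα cells were -0.49 ± 0.23 for Nr0b1 (adjusted p = 0.0784), -0.39 ± 0.15 for Dppa5a (adjusted p = 0.0471), -0.23 ± 0.16 for Dnmt3l (adjusted p = 0.215), -0.49 ± 0.25 for Zfp980 (adjusted p = 0.115) and -0.90 ± 0.15 for Zfp640 (adjusted p = 5.92e-04). The call of Dppa5a was lost under 9 of 17 alternatives, among them the fits without null replicate 1 or any flox or null Eα array (-0.35 to -0.41). Without null Eα replicate 2, Nr0b1 and Zfp980 were called at -0.71 and -0.72, and with each chromosome centred Nr0b1 was called at -0.57. The genes that differed most from flox in both lines alike were Tnc, Thbs1, Anxa1, Usp17ld (4.97 ± 0.47 in null cells) and Peg10 (-5.81 ± 0.10 in null cells).

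By list, 26 of 27 pluripotency genes moved back, as did 13 of 23 desmosome and tight junction genes, 11 of 23 integrin and matrix genes, 11 of 20 mesenchymal genes, 10 of 16 germline genes and 7 of 14 fibroblast markers. Many members of these lists still differed from flox alike in both lines. They were 20 pluripotency, 3 desmosome and tight junction, 13 integrin and matrix, 12 mesenchymal, 8 germline and 12 fibroblast genes. Of 21 Wnt/β-catenin targets 1 moved back, Notum, while 8 differed from flox alike in both lines. Independent calls would give 957 genes up and then down and 780 down and then up, against 1772 and 1721 counted. For genes alike in both lines they would give 1696 up and 1806 down, against 3801 and 4863. Across genes, which are not independent replicates, the differences of null and of null Eα from flox correlated at r = 0.80, against 0.50 for simulated unchanged groups that share the flox arrays. The differences of null from flox and of null Eα from null correlated at r = -0.57, against -0.50 in simulation. The covariances were 0.443 and -0.228, against 0.00692 and -0.00689 in simulation, and shared arrays add that much with or without real changes, so they account for little of either covariance. In 100 simulations of unchanged groups the overlaps of calls were at most 1 gene. Without real changes hardly any gene can be called, so this sets no bound on the overlaps counted here. Groups of 3 arrays leave too few to split the shared arrays. For the counts of overlapping calls, unlike the replicate noise in the covariances, the part that comes from sharing arrays was therefore not separated.

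**Figure D3:**
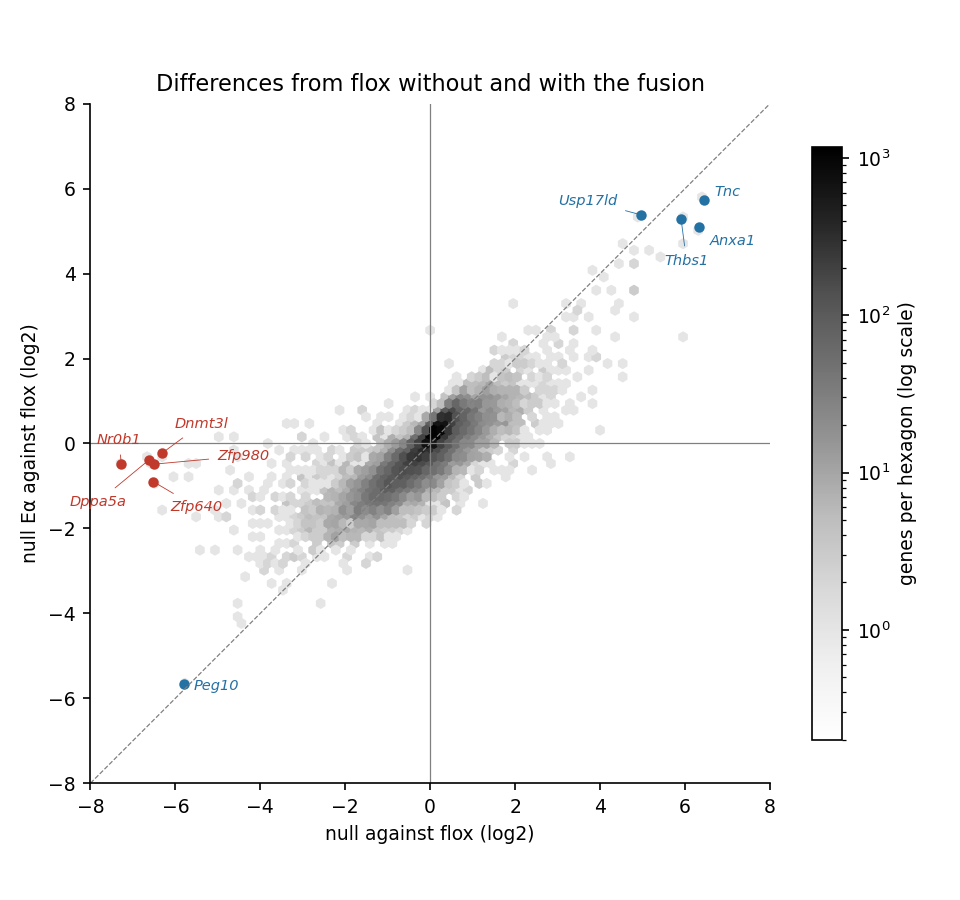
Log2 difference from flox in null cells (horizontal axis) and in null Eα cells (vertical axis) for 19938 genes, shaded by the number of genes, with 10 genes marked. The 5 marked genes that moved back toward flox, such as Nr0b1 (-7.27 and -0.49), lie near 0 on the vertical axis, and the 5 alike in both lines, such as Tnc (6.45 and 5.74), lie along the diagonal.

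Genes of some chromosomes shifted together. Against genes of other chromosomes of like mean level, the 559 brighter genes of chromosome 8 lay at -0.42 in null cells (95% interval over genes -0.51 to -0.32) and at -0.40 in null Eα cells, both against flox. The intervals given here carry no spread between cultures or lines. In null Eα cells the 443 brighter genes of chromosome 6 lay at -0.37 (-0.47 to -0.25) and the 876 of chromosome 11 at -0.38 (-0.42 to -0.31), while in null cells these shifts were -0.04 for both. The 465 brighter genes of chromosome 3 lay at 0.31 in null cells and 0.20 in null Eα cells, and the 250 of chromosome 18 at 0.17 and 0.21. Among the genes named here, Cdh1, Mcm5 and Apela lie on chromosome 8, Nanog, Gdf3, Mcm2, Col1a2, Cald1, Hk2, Herc6 and Peg10 on chromosome 6, Jup, Axin2, Notum, Znrf3, Pecam1, Sox15, Col1a1, P4ha2 and Krt19 on chromosome 11, and Slc39a8, Cgn, Terc, Sohlh2, Tdrkh and Wls on chromosome 3. Ctnna1, Lox, Dsc2 and Cdh2 lie on chromosome 18.

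**Figure D4:**
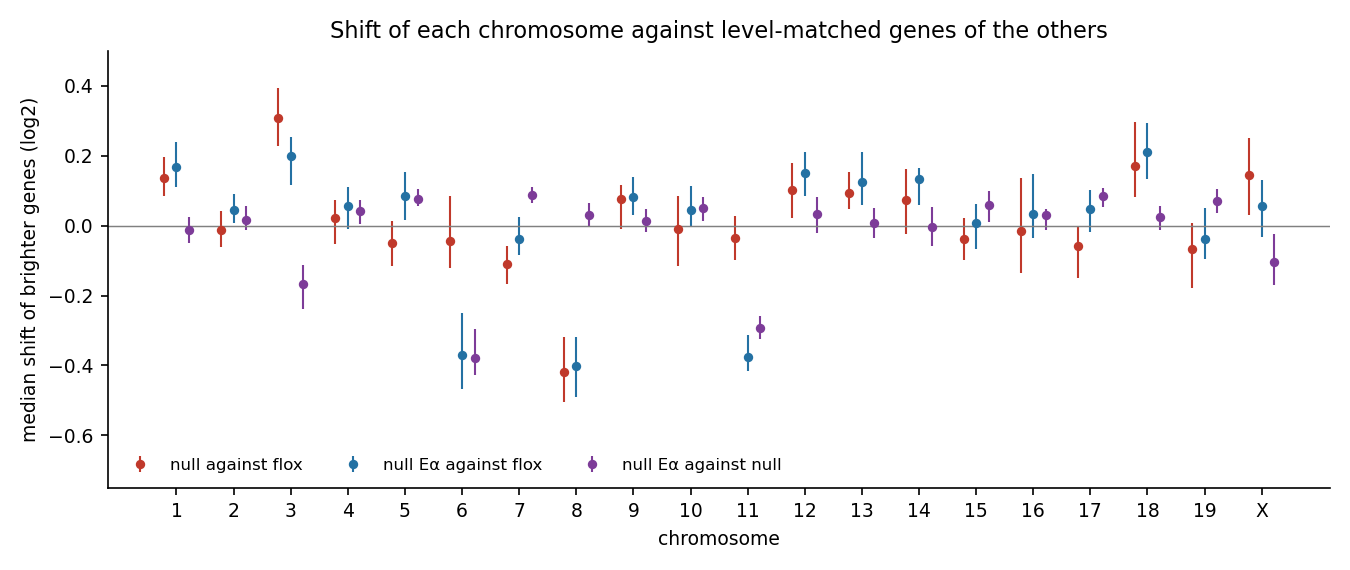
Median log2 shift of each chromosome's brighter genes (mean level above the median) against level-matched genes of other chromosomes (vertical axis) by chromosome (horizontal axis) in the 3 comparisons. Bars are 95% bootstrap intervals over genes, not over arrays. Chromosome 8 lay at -0.42 in null against flox, and chromosomes 6 and 11 at -0.38 and -0.29 in null Eα against null.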

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

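Of the tests in this part, the spread of the pluripotency falls, the spread of the fibroblast gains, the level-matched shifts and copies of chromosomes 8, 6 and 11, and the blocks of chromosome 8 in null Eα cells were chosen after the results they examine had been seen. The other blocks were fixed after the chromosome shifts but before the block values had been seen, and the remaining tests beforehand.

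A difference between the lines marked 219 genes that were called in opposite directions against flox in null and in null Eα cells and were also called between these lines. By the rule used, these 219 are part of the 3493 genes counted as moved back, although they passed flox. Genes of this set named after their values were seen include Gprc5c, an orphan receptor (1.31 ± 0.36 in null and -1.39 ± 0.36 in null Eα cells), Kctd12b (1.14 ± 0.23 and -1.01 ± 0.23), the growth factor gene Pdgfc (-0.92 ± 0.15 and 0.93 ± 0.15) and Tia1, an RNA-binding protein (1.32 ± 0.11 and -0.86 ± 0.11). Gprc5c lies on chromosome 11, Tia1 on chromosome 6 and Pdgfc on chromosome 3, whose brighter genes shifted by -0.38, -0.37 and 0.20 in null Eα against flox.

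Features outside the gene comparisons also carried signal. Of the 12146 features that the annotation used here pairs with no gene, 1775 were called at 2-fold or more in null against flox, 966 higher and 809 lower, and 1886 in null Eα against flox, 941 higher and 945 lower (limma with Benjamini-Hochberg adjustment over these features). The annotation does not say what they measure.

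The fall of the pluripotency list in null cells had a median of -3.17 log2 units. Diluting cells of another type that express none of the members would lower every member alike. Of the 27 members, 17 lay over 1 log2 unit and over 3 standard errors from the list's median. This argues against dilution by such cells as the whole cause. Cells that express part of the list would lower its members unequally as well, so the test cannot decide about them. The narrower spread of values on the null arrays would lower random lists of like level as well, and the list lay at -3.026 relative to the median of such lists, with 0 of 10000 as low. A loss of pluripotency transcripts in the null line remains a candidate explanation. Whether it comes from the missing β-catenin or from the line was not tested, since the labels give no independent lines.

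Fibroblast markers were higher in both lines than in flox cells, where the labels name gelatin-coated plates and no feeder layer, and no sort that would remove other cells. If the signal came from 1 other kind of cell at different shares, the 12 markers that rose in both lines would have kept 1 ratio between the lines. The spread of that log2 ratio over markers (SD 0.482, from -1.98 to -0.33) was 2.25 times its median standard error of 0.214, between the bound of 2 for a shared source and that of 3 against it, so such a source and expression by the stem cells themselves cannot be told apart. Abundant fibroblast transcripts reached high levels in null cells, 11.02 for Col1a2 and 11.92 for Acta2, which the mesenchymal list holds too, whereas Fn1, high in flox cells already, fell. Normalization alone is argued against, since the list lay above level-matched random lists by at least 2.372 in each line.

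Shifts of the genes of a chromosome were the third pattern. A level-dependent normalization is argued against by the level-matched shifts of -0.42 for chromosome 8 in null cells and -0.402, -0.369 and -0.376 for chromosomes 8, 6 and 11 in null Eα cells, taken over brighter genes after the shifts over all genes (-0.13, -0.17, -0.06 and -0.16) had been seen, because dim features carry little signal. Over all genes, chromosome 6 would have met the bound of 0.1 for normalization, and every shift would have met the bound of 0.2 against a change in copies. A few neighbouring groups of genes are argued against in null Eα cells for chromosomes 11 and 8, where 10 and 9 of 10 blocks lay below -0.2, and stay open for chromosome 8 in null cells and chromosome 6 in null Eα cells, with 8 and 7 of 10 blocks. A different number of copies of the chromosome, which would be 0.58 for 3 copies against 2, stays open for each of them, since it turns on the brighter genes, and no DNA measurement was used here.

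Other groupings of the arrays were counted for each comparison. Of the 10 splits of the 6 flox and null arrays 1, the real one, gave 11004 called genes, and the highest other gave 0. For null Eα and flox 1 split gave 12694 and the highest other 0, and for null Eα and null 1 split gave 6330 and the highest other 4. With 10 splits a share under 0.05 cannot be reached.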

How the results depend on the processing

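Centring each chromosome was chosen after the data were seen, and the other alternatives were fixed beforehand. The gene values counted here are those of named genes, many chosen for large changes or small p in the same data. Their shares therefore do not speak for gene calls in general. Over processing alternatives, 1605 of 1646 gene values kept their side of the threshold without a reversal, 24 lost the call, 15 gained it and 2 reversed. A change of sign counted as a reversal only with a call in either fit. Uncalled values that changed sign, as Cdh1 in null against flox with each chromosome centred, count as kept. With 1 array left out, 1805 of 1881 did, 58 lost the call, 17 gained it and 1 reversed. For lists, 474 of 504 did (25 lost, 5 gained), and with 1 array left out 541 of 567 (16 lost, 10 gained). Arrays per group limited the precision, and signal over background could not be judged without detection calls.

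At an adjusted p under 0.01, 3721 genes were called in null Eα against null and 2230 moved back toward flox, against 6330 and 3493. With a 2-fold minimum the counts were 3045 for null against flox, 2386 for null Eα against flox, 963 for null Eα against null, 662 moved back and 1681 alike, since fewer genes can pass a stricter rule. With an estimated correlation, camera called 0 lists in null against flox, 0 in null Eα against flox and 0 in null Eα against null. Quantile normalization left 7 lists called in null Eα against null, against 13, and leaving out dim genes left 8. Leaving out dim genes also gave 8430 calls in null Eα against flox, since fewer genes were tested. Centring on the median gave 42.2% lower calls in null against flox, against 52.0%. With each chromosome centred, in null Eα against flox, Cdh1 was 0.0657 (adjusted p from 0.00146 to 0.511 over 17 alternatives), against -0.26, since most of chromosome 8 was lower, and Meox1 was 0.34, against -0.02. The cause of the other changes was not tested.

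With each array left out in turn, called genes ranged from 9535 to 11652 in null against flox, 10783 to 13041 in null Eα against flox and 4726 to 7859 in null Eα against null. Genes that moved back ranged from 2828 to 3863 and genes alike from 7267 to 8764. Lists called in null Eα against null ranged from 8, without null replicate 3, to 14. Uty in null Eα against flox ranged from -0.73 to 0.27, the latter called and without null Eα replicate 2, against -0.36.

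The arrays share replicate numbers. Same-numbered arrays deviated together by more than 0.1 in 3 of 9 pairs (-0.03 to 0.26), short of the rule that every pair must, so the numbers were not read as pairs. That 8 of 9 pairs lay above 0 and 6 of 9 arrays correlated best with their own number is a hint from the data, not the design, that something was shared. With the replicate block, 11298, 12935 and 6602 genes were called in null against flox, null Eα against flox and null Eα against null, 3572 moved back and 8963 were alike, and 6, 6 and 12 lists were called. Background correction at the probe level was not run, because probe-level files were not used here.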

Other observations

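Of 18 imprinted genes 6 rose and 7 fell in null cells, with a median of -0.08, and the list was not called (camera adjusted p = 0.858). Of the 5 members given here, all but Meg3 and Peg10 were named after their values were seen. Meg3 and Rian, maternally expressed noncoding RNAs of 1 cluster on chromosome 12, rose in null cells by 4.52 ± 0.17 and 3.79 ± 0.27 (limma adjusted p = 1.54e-08 and 8.76e-07) and in null Eα cells by 1.57 ± 0.17 and 0.96 ± 0.27. Between the lines they differed by -2.95 ± 0.17 and -2.83 ± 0.27. On chromosome 6 the paternally expressed neighbours Peg10 and Sgce, and Mest, changed by -5.81 ± 0.10, -2.16 ± 0.17 and -2.99 ± 0.09 in null cells. In null Eα cells they changed by -5.66 ± 0.10, -2.16 ± 0.17 and -2.70 ± 0.09. The brighter genes of chromosome 6 shifted by -0.04 in null and -0.37 in null Eα cells.

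Transcripts of the sex chromosomes were read as a check of the lines. Xist, the RNA of X inactivation, had log2 values of 3.96 to 4.41 on the flox arrays and 5.21 to 6.03 on the other arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty had 7.93, 5.17 and 6.46 on null Eα replicate 2, against 9.18, 6.55 and 8.25 on replicate 1 and 9.33, 7.72 and 8.46 on replicate 3. The calls of Xist, Eif2s3y and Kdm5d between null Eα and null were lost under 7 of 16, 9 of 17 and 9 of 17 alternatives, those of Xist (-0.39) and Kdm5d (-0.88) also without null Eα replicate 2.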
